A study of Mus musculus with 3 samples.

How the data were processed

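The data were 3 mouse array comparative genomic hybridisations, each of ductal breast carcinoma DNA against tail DNA of the conditional mutant mice, per the labels. Tumour DNA was labelled with Cy5 (red) and tail DNA with Cy3 (green), per the labels, and the direction of every ratio rests on those labels. Each group held 1 array: a Brca1 +/+ tumour (called wildtype here), a flex2/flex2 tumour and a flex2/FH-I26A tumour. The titles of all 3 carry the prefix PC, which the labels do not explain and which was not interpreted, so that wildtype refers to Brca1 alone.

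The deposited scanner files hold each spot's intensity. The processed intensity in both channels had been background-subtracted, spatially detrended and linearly dye-normalised by the authors, per the file headers, with Agilent Feature Extraction, which the submitters' processing notes also name; the version was 9.1.3.1 for the wildtype array and 9.5.3.1 for the other arrays, per the file headers. The files also hold the log10 ratio of red over green that this software computed, per the file headers. The deposited value table holds log2 ratios that equalled the scanner's log ratio on the log2 scale within 0.0001 for 100%, 99.4% and 99.4% of features in the wildtype, flex2/flex2 and flex2/FH-I26A arrays. So its scale and direction were settled, and the same equality shows that it was not centred further. Its column medians were 0.00, 0.01 and 0.01.

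The log2 ratio of processed red over green signal was computed here for every spot that is no control. Spots with an outlier mark in the files, 0.645%, 5.88% and 15.3% of features, were left out, spots of the same probe were averaged, and each array was centred on the median of its autosomal probes, with no loess or quantile step. Saturated spots were kept. Over 99% of features were well above background in both channels (99.8% in each array), and the median spot signal was 15.9, 13.5 and 11.6 times its local background in red and 10.9, 7.76 and 8.95 times in green. The number of arrays limits the precision.

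Probe positions on mm8 were taken from the files of the flex2/flex2 and flex2/FH-I26A arrays and joined to the wildtype array by probe, because the wildtype file gives other positions and names no build. Probes on chromosomes 1 to 19 and X were used. Features without a position (1964) and the 849 on Y, mitochondrial or unplaced sequence stayed out of the calls.

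Each chromosome was cut into segments by exact optimal partitioning for changes in the mean, with a penalty of 10 times the log of the number of probes times the noise variance, and at least 5 probes per segment. Noise was the SD of a single probe, derived from the robust SD (interquartile range over 1.349) of differences between neighbouring probes. That SD was scaled down because a difference carries the noise of both probes. A segment with a mean log2 ratio of at least 0.2 was called a gain and of at most -0.2 a loss. Means of at least 1 were high-level and of at most -1 deep, and a chromosome with at least 80% of its probes in gains, or in losses, counted as a whole-chromosome change. The steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, with R 4.3.3 and limma 3.58.1 for the normexp alternative, and matplotlib 3.10.9 for figures.

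The segmentation was tested on simulated data made from each array's residuals around its segment means, in shuffled order. Without events it made 0 calls. Shuffling removes any regional trend along a chromosome, so false calls from such a trend were not measured. Events of 200 probes with a shift of 0.3 were recovered in 100%, 100% and 87.2% of cases for the wildtype, flex2/flex2 and flex2/FH-I26A arrays, events of 50 probes with a shift of 0.6 in 100%, 100% and 94.9%, and events of 20 probes with a shift of 1 in 100%, 100% and 97.5%. Events of 50 probes with a shift of 0.3, and of 5 probes with a shift of 1, were recovered in 0% on every array.

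The files name no genes, and the gene table used here is on GRCm38, another build. It was used for gene names and for the chromosome of each gene only, and 204 of the 213 distinct names in 9 gene lists, fixed before the data were examined, were matched. The rule for named genes, also fixed before the data were examined, was to name Brca1 and Trp53, list genes in called segments by the size of the segment mean (up to 10 oncogenes in gains, 10 suppressors in losses and 5 of each repair list), genes inside high-level, deep and short strong segments, and list genes called in opposite directions. Apart from Brca1 and Trp53, its parts need gene positions on the build of the files and could not be applied. The other genes named were chosen after the values were seen, as list members on whole changed chromosomes or on chromosomes with no call, and are tied to a chromosome only. For the same reason the planned values of probes within 50 kb of Brca1 and Trp53, and the planned percentiles of gene lists among random lists, were replaced by values of chromosome 11 and by counts of list genes per chromosome.

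Overlap of calls between tumours was described as a count of shared probes among 10000 circular shifts, with no p-value. The alternatives were normexp with an offset of 50, applied to the median spot signals because the files used here hold no mean signals, the authors' value table, centring on the mode, keeping spots with outlier marks, only probes well above background, penalty factors of 5 and 20, segments of at least 3 and at least 10 probes, and call thresholds of 0.1 and 0.3. A planned correction for GC content was not run, since probe sequences and a genome of the build were not used here.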

Results

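Copy number was measured by array comparative genomic hybridisation in 3 mouse ductal breast carcinomas. Each tumour's DNA was hybridised together with tail DNA on its own Agilent oligonucleotide array, so that the ratio of the dyes at a probe reports the tumour's DNA dose relative to tail at that position. The tumours carried different Brca1 genotypes. The labels of all 3 share the prefix PC, which they do not explain. Other engineered alleles were not determined, and wildtype below means Brca1 +/+ only. The first was Brca1 +/+, the second was homozygous for flex2, a conditional Brca1 allele, and the third combined flex2 with FH-I26A, an allele with a changed residue in the RING domain, the part of the protein that carries its ubiquitin ligase activity. The study's title sets that ligase activity against phosphoprotein binding by the BRCT domain as parts of tumour suppression. The profiles show which chromosome regions were gained or lost in a tumour of each genotype.

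There was 1 array per genotype, so no difference between genotypes has a replicate check, and no test between genotypes was made. Standard errors (SE, over probes) measure the scatter of probes within a single array and treat neighbouring probes as independent. They leave out regional trends and so understate the technical error. Means over 1 Mb outside calls had SDs of 0.08, 0.05 and 0.09 in the wildtype, flex2/flex2 and flex2/FH-I26A arrays. Probes used numbered 231180 in the wildtype tumour, 219253 in the flex2/flex2 tumour and 197371 in the flex2/FH-I26A tumour. The probe noise, as an SD on the log2 scale, was 0.19, 0.22 and 0.27 in the same order, and the median distance between probes was 7.90, 8.16 and 8.75 kb. Each tumour was hybridised on an array of its own and the wildtype array was read with an older software version, so batch and genotype cannot be told apart. Coordinates are on the mouse build mm8.

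**Figure D1:**
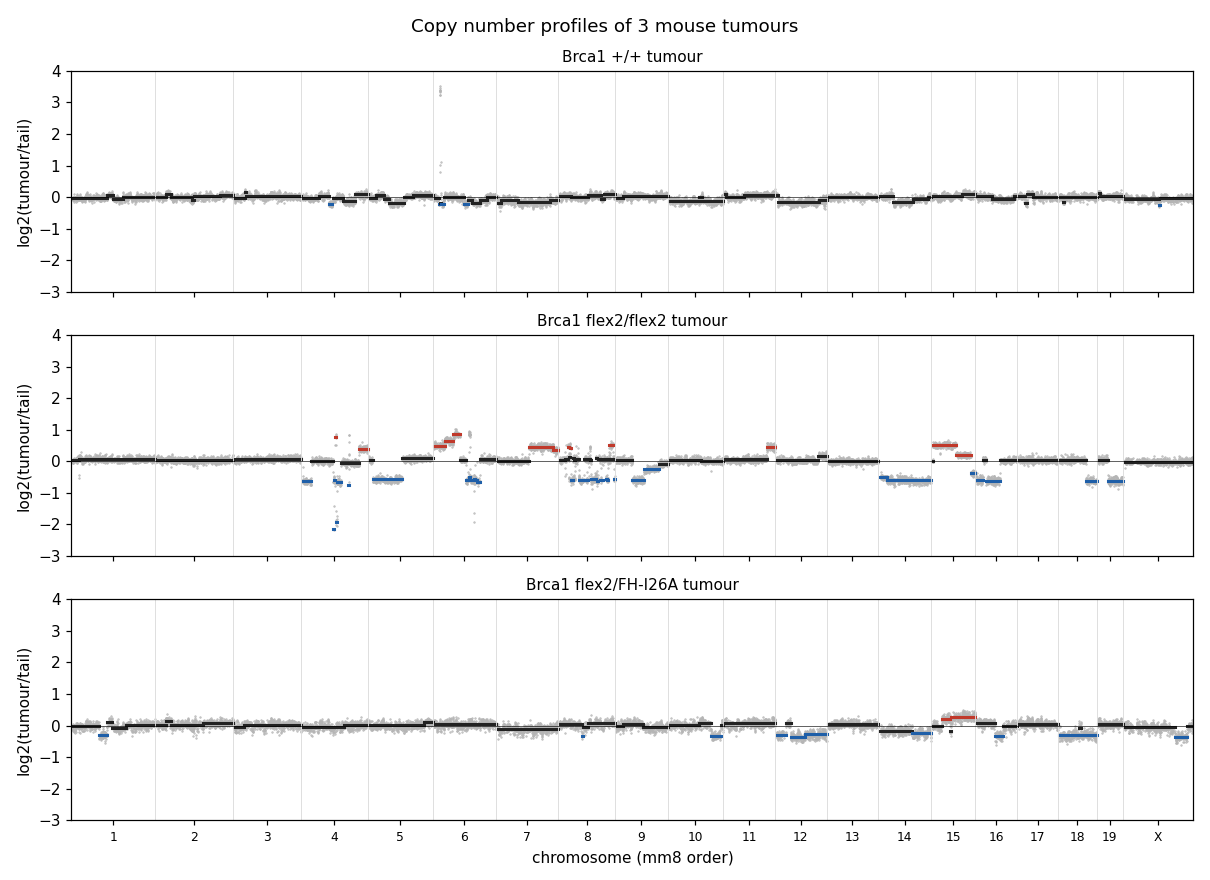
Copy number along the genome in the 3 tumours: the x axis is position by chromosome in mm8 order and the y axis is log2(tumour/tail). Grey points are means of 20 neighbouring probes and lines are segment means, red for gains, blue for losses and black for segments without a call; the wildtype tumour has a narrow peak at 3.37 on chromosome 6, and the flex2/flex2 tumour has calls on 13 chromosomes.

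Chromosome 11, which carries both the engineered gene Brca1 and Trp53, held no called loss in any of the 3 tumours, although a penalty factor of 5 called 5 probes lost there in the wildtype tumour. Its mean log2 ratio was 0.05 in the wildtype tumour, 0.14 in the flex2/flex2 tumour and 0.07 in the flex2/FH-I26A tumour. The sole call there was a gain in the flex2/flex2 tumour, from 101.83 to 121.8 Mb, with a mean of 0.45 (SE 0.00520, 2262 probes). The lowest means of 5 neighbouring probes on the chromosome were -0.67, -0.46 and -0.86 in the same order of tumours, and in each of these windows 1 probe lay below -1 while the median was -0.04, -0.11 and 0.16. Probes lay a median of 7.22 to 7.86 kb apart on this chromosome, and simulated losses of 5 probes with a shift of 1 were never recovered, so a deletion of single exons was not detectable. Probes were not assigned to Brca1 or Trp53 themselves, since the gene table used here is on another genome build.

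With the call threshold of 0.2, 0.924% of the wildtype tumour's probes were called gained or lost, and chromosome 6 held a high amplification. Between the thresholds of 0.1 and 0.2, 13 further segments lay on the side of losses and 3 on the side of gains. The amplified segment ran from 16.63 to 18.55 Mb with a mean log2 ratio of 3.37 (SE 0.0354, 192 probes), 10.3 times the tail level. With normexp background correction the highest segment of the chromosome had a mean of 4.19, so the size of the amplification depends on the processing. A smaller pair of high segments followed, from 19.32 to 19.55 Mb with a mean of 1.04 (SE 0.0578, 8 probes) and from 19.98 to 20.51 Mb with a mean of 1.18 (SE 0.0873, 20 probes). These 3 segments were all the gains called in this tumour and covered 2.68 Mb, or 0.0952% of probes.

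Losses in the wildtype tumour were shallow and covered 0.829% of probes, or 27.8 Mb. Both sides of the chromosome 6 amplification were called lost, from 14.52 to 16.59 Mb with a mean of -0.23 and from 20.53 to 25.94 Mb with a mean of -0.21, and a short loss at -0.38 lay between the smaller high segments. The other losses were on chromosome 6 from 72.74 to 82.55 Mb, on chromosome 4 from 64.95 to 72.83 Mb and on chromosome X from 83.62 to 85.91 Mb, with means of -0.21, -0.23 and -0.26. Chromosomes 7, 10 and 12 had means of -0.13, -0.11 and -0.14 and no call. The losses rested on the threshold: 12 probes were called lost with a threshold of 0.3 in place of 0.2, and 40918 with a threshold of 0.1, against 1916.

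**Figure D2:**
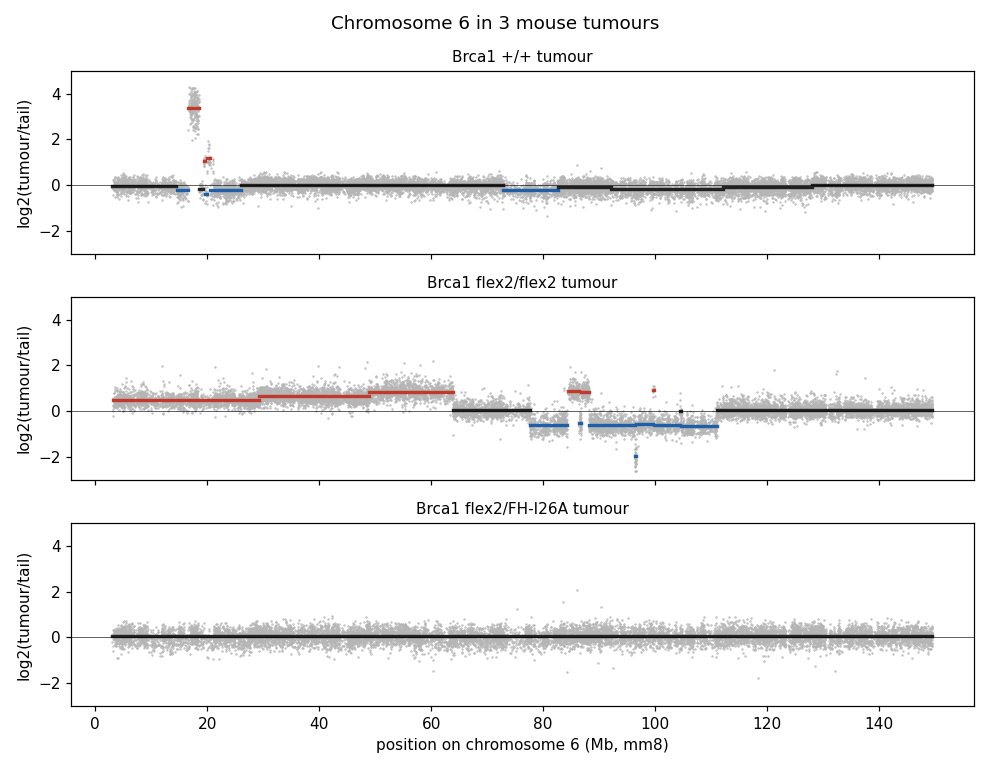
Chromosome 6 in the 3 tumours: the x axis is position in Mb (mm8) and the y axis is log2(tumour/tail) per probe in grey, with segment means as lines, red for gains, blue for losses and black for no call. The wildtype tumour reaches a mean of 3.37 from 16.63 to 18.55 Mb, the flex2/flex2 tumour is gained from 3.1 to 63.84 Mb, and the flex2/FH-I26A tumour has a single segment at 0.04.

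The flex2/flex2 tumour had the most altered genome of the 3, with 11.6% of probes gained and 18.9% lost. It held 60 called segments, 20 gains and 40 losses, on 13 chromosomes. Chromosome 14 was lost along its whole length, with a mean log2 ratio of -0.59 (SE 0.00269, 9997 probes); it carries the tumour suppressor Rb1, the BRCA1-associated deubiquitinase gene Bap1, the chromatin remodelling gene Pbrm1 and Fhit. Chromosome 15, which carries the oncogene Myc and its neighbour Pvt1, was gained over 82.9% of its probes, at 0.52 from 4.26 to 58.4 Mb and at 0.20 from 58.41 to 93.13 Mb, and lost at -0.39 over its last 10.35 Mb. Where Myc lies among these segments was not determined.

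Further large losses in the flex2/flex2 tumour covered chromosome 5 from 11.89 to 80.39 Mb at -0.57, chromosome 9 from 41.03 to 68.8 Mb at -0.59 and, less deeply, from 68.82 to 104.23 Mb at -0.25, chromosome 16 from 25.7 to 58.41 Mb at -0.61, chromosome 18 from 65.7 to 90.73 Mb at -0.61 and chromosome 19 from 27.04 to 61.32 Mb at -0.62. The largest gains besides those of chromosome 15 were on chromosome 7 from 75.5 to 132.83 Mb at 0.46 and on chromosome 6, where the log2 ratio rose in steps from 0.50 to 0.65 and 0.85 between 3.1 and 63.84 Mb. There were 3 deep losses, on chromosome 4 from 74.93 to 75.67 Mb at -2.15 (SE 0.0831, 32 probes) and from 81.15 to 82.86 Mb at -1.91 (SE 0.0463, 121 probes), and on chromosome 6 from 96.32 to 96.59 Mb at -1.97 (SE 0.0668, 39 probes). All 3 lay within or beside shallower losses at -0.55 to -0.65, except that a gain at 0.76 from 79.27 to 81.13 Mb bordered the second loss on chromosome 4. With normexp background correction there were 3 deep losses and 4 high-level gains against 0, and 1 whole-chromosome change in place of 2 was counted with centring on the mode, where chromosome 15 no longer counted, the second segment of chromosome 15 having stood at the threshold.

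Chromosome 8 of the flex2/flex2 tumour was broken into 40 segments, which alternated between losses, gains and segments without a call. The 15 losses had means from -0.65 to -0.52, the 6 gains from 0.41 to 0.52 and the 19 segments without a call from 0.05 to 0.14. The chromosome held 39 of the tumour's 89 breakpoints with 4.90% of its probes, whereas the wildtype and flex2/FH-I26A tumours had 5 and 4 segments there.

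**Figure D3:**
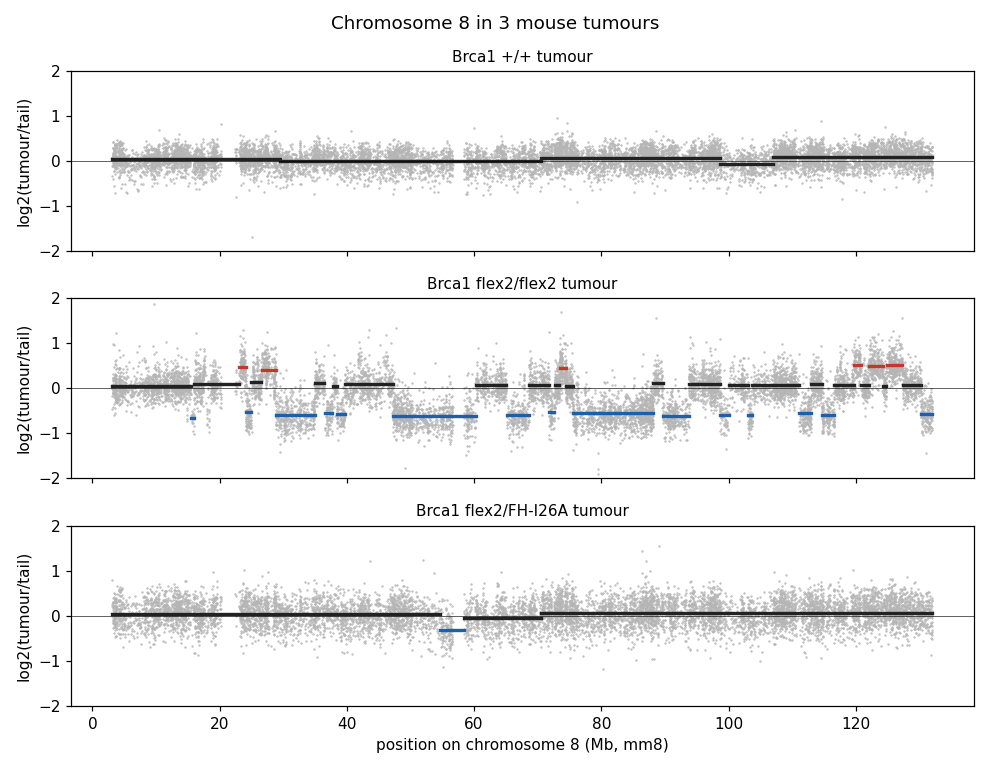
Chromosome 8 in the 3 tumours: the x axis is position in Mb (mm8) and the y axis is log2(tumour/tail) per probe in grey, with segment means as lines, red for gains, blue for losses and black for no call. In the flex2/flex2 tumour 40 segments alternate between losses at -0.65 to -0.52, segments without a call and gains at 0.41 to 0.52.

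The flex2/FH-I26A tumour had 3.19% of probes gained and 11.9% lost, mostly as changes of whole chromosomes, and no high-level gain or deep loss. Chromosome 12 was lost over 91.1% of its probes, with a chromosome mean of -0.27 (SE 0.00329), and carries Akt1 and Mycn as well as the homologous recombination genes Rad51b and Xrcc3. Chromosome 18 was lost over 95.5% of its probes, with a mean of -0.29 (SE 0.00359), and carries the tumour suppressors Apc, Smad2 and Smad4. Chromosome 15 was gained over 81.0% of its probes, with a mean of 0.21 (SE 0.00341). The stretches outside the calls were not matched to genes, so any single gene of these 3 chromosomes could lie in them.

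The remaining losses of the flex2/FH-I26A tumour were on chromosome 1 from 65.28 to 84.05 Mb at -0.31, chromosome 8 from 54.72 to 58.37 Mb at -0.32, chromosome 10 from 100.57 to 123.68 Mb at -0.32, chromosome 14 from 79.44 to 123.95 Mb at -0.24, chromosome 16 from 45.69 to 64.18 Mb at -0.33 and chromosome X from 122.04 to 151.32 Mb at -0.36. In the wildtype tumour the 3 regions lost on chromosome 12 had means of -0.10, -0.19 and -0.12, and the region lost on chromosome 10 had a mean of -0.15; both regions lost on chromosome 18 lay at 0.00 and 0.02 there. The median log2 ratio over lost probes was -0.31 in the flex2/FH-I26A tumour and -0.60 in the flex2/flex2 tumour, and over gained probes 0.28 and 0.46. With a threshold of 0.3 the flex2/FH-I26A tumour had 0 gained probes and 0 whole-chromosome changes. The rest of chromosome 14, from 3.91 to 79.42 Mb, lay at -0.16 without a call. Chromosome 14 was lost over 100% of its probes with normexp or a threshold of 0.1. Chromosome 15 no longer counted as a whole-chromosome change with a penalty factor of 5.

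Overlap between tumours was described over the 186999 probes common to the 3 arrays, against 10000 circular shifts of the calls of 1 tumour along the genome. The flex2/flex2 and flex2/FH-I26A tumours were both gained on chromosome 15 from 25.81 to 44.66 Mb and from 47.08 to 93.13 Mb, which made 4786 probes, or 80.5% of the smaller set of gained probes; 239 of the 10000 shifts gave as many. Both were lost on parts of chromosomes 8, 14, 16 and 18, 5549 probes in all, and 2518 shifts gave as many. All 189 common probes gained in the wildtype tumour were also gained in the flex2/flex2 tumour, at 0.52 against 3.35 over the main amplified segment, and 1008 shifts gave as many. The losses shared by these tumours covered 274 probes on chromosome 6, and 4815 shifts gave as many. The wildtype and flex2/FH-I26A tumours shared 0 gained and 0 lost probes. Shared losses depended on the settings. Over the common probes of each pair, a threshold of 0.1 gave 18159 for wildtype and flex2/FH-I26A against 0, 7966 for wildtype and flex2/flex2 against 328, and 11411 for flex2/flex2 and flex2/FH-I26A against 5558. A threshold of 0.3 gave 0, 0 and 905 in the same order. A penalty factor of 5 gave 1929 shared losses for wildtype and flex2/FH-I26A, and only probes well above background gave 88. The shared gain on chromosome 15 included the segment at the threshold in the flex2/flex2 tumour, and over the 2 arrays' own common probes it fell from 4808 to 1994 probes with centring on the mode and to 0 with a threshold of 0.3.

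Chromosomes 2, 3, 13 and 17 had no call in any tumour, which covers 40 of the 204 listed genes that were matched to a chromosome. Among them were the 53BP1 pathway genes Trp53bp1 and Rif1 and the oncogenes Pik3ca, Nras and Notch1. With a threshold of 0.1, chromosomes 2, 3 and 17 held calls in the wildtype tumour, on segments at -0.104, 0.159 and -0.188. That left chromosome 13 with 8 listed genes and none of those just named. Of the 53 oncogenes, 5 lay on a whole changed chromosome in the flex2/flex2 tumour, all on chromosome 15, and 7 in the flex2/FH-I26A tumour, the same 5 on the gained chromosome 15 with Akt1 and Mycn on the lost chromosome 12. Chromosome 15 of the flex2/flex2 tumour was lost over its last 10.35 Mb, and which of the 5 lie there was not determined. Of the 41 tumour suppressors, 4 lay on the lost chromosome 14 in the flex2/flex2 tumour, and 3 lay on the lost chromosome 18 in the flex2/FH-I26A tumour.

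Of the 35 homologous recombination genes, 0 lay on a whole changed chromosome in the flex2/flex2 tumour, and 4 did in the flex2/FH-I26A tumour, Rad51b, Xrcc3 and Fancm on chromosome 12 and Rbbp8, which encodes the end resection factor CtIP, on chromosome 18. Chromosomes called in part carried 28 of the 35 in the flex2/flex2 tumour and 4 in the flex2/FH-I26A tumour, and chromosomes without a call carried 7 and 27. Genes on chromosomes called in part were likewise more numerous in the flex2/flex2 tumour among oncogenes (30 against 8), suppressors (27 against 12) and end joining genes (13 against 8). Any call made a chromosome count, such as the loss of 0.130% of chromosome 1 in the flex2/flex2 tumour. That tumour had calls on 13 chromosomes and 30.6% of probes, the flex2/FH-I26A tumour on 9 and 15.1%. These counts therefore describe chromosomes and are no result about repair genes. Of the 21 end joining and 53BP1 pathway genes, 2 lay on a whole changed chromosome in the flex2/flex2 tumour, Parp2 on chromosome 14 and Xrcc6, which encodes Ku70, on chromosome 15, and in the flex2/FH-I26A tumour Xrcc6 was the 1 such gene. Of the 11 genes of RING and BRCT partners of Brca1, Bap1 lay on the lost chromosome 14 of the flex2/flex2 tumour and Rbbp8 on the lost chromosome 18 of the flex2/FH-I26A tumour. The counts for the flex2/flex2 and flex2/FH-I26A tumours were 4 and 5 of 16 luminal mammary genes, 2 and 2 of 11 basal mammary genes, 1 and 1 of 18 spindle checkpoint and centrosome genes, and 3 and 3 of 12 antigen receptor genes. In the flex2/flex2 tumour the luminal, basal and spindle genes counted were all on chromosome 15, which was also lost over 15.7% of its probes. Genes were not placed within it, so any gene counted there, Xrcc6 included, could lie in the gain or in the loss. The wildtype tumour had no whole changed chromosome, so each of its counts was 0. With a threshold of 0.1, where its chromosome 10 was lost over 91.3% of probes, it had 3 oncogenes, 2 suppressors, 1 luminal gene and 1 partner gene on it. Chromosome 15 of the flex2/flex2 tumour no longer counted as a whole-chromosome change with centring on the mode, with outlier spots kept or with a threshold of 0.3. The counts of oncogenes, luminal, basal and spindle genes were then 0 there, and that of end joining genes was 1. With a threshold of 0.3 every count of the flex2/FH-I26A tumour was 0. In the flex2/FH-I26A tumour a threshold of 0.1 gave 16 oncogenes against 7, 7 suppressors and 6 antigen receptor genes against 3 each, 7 homologous recombination genes against 4, 3 end joining, 3 spindle and 3 RING and BRCT partner genes against 1 each. Normexp gave 7 suppressors, 6 antigen receptor genes, 2 end joining and 2 partner genes. A penalty factor of 5 gave 2 oncogenes, 1 luminal gene against 5, 0 basal genes against 2, and 0 end joining and 0 spindle genes.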

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

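The tests in this part were chosen after the result was seen, except the correlation of each probe with its neighbour on the other array, which was chosen before that correlation was seen.

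Regions of at least 1 Mb with opposite calls in a pair of tumours drew attention, and the differences were not tested. The flex2/flex2 tumour was gained where the wildtype tumour was lost on chromosome 6 over 2.06 Mb from 14.52 to 16.59 Mb (0.46 against -0.23) and over 5.39 Mb from 20.55 to 25.94 Mb (0.52 against -0.21). The flex2/FH-I26A tumour was gained where the flex2/flex2 tumour was lost over 10.35 Mb of chromosome 15, from 93.13 to 103.48 Mb (0.28 against -0.38).

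Mitochondrial probes, which entered no comparison, had mean log2 ratios of 0.50 in the wildtype tumour, 1.16 in the flex2/flex2 tumour and 1.22 in the flex2/FH-I26A tumour; there were 2 such probes, and 1 of their spots in the flex2/flex2 array and both in the flex2/FH-I26A array carried an outlier mark.

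The 599 Y probes of the wildtype array had a median net signal of 47.9% of the autosomal median in the tumour channel and 47.5% in the tail channel, against 7.38% to 17.0% on the other arrays. A male animal would lower the X probes by about 1 log2 unit, but in the tail channel they lay at 0.0115 against autosomal probes relative to the other arrays, with an SD of 0.00670 over the 19 autosomes. Negative controls had 1.58% of the autosomal signal in the tumour channel and 10.97% in the tail channel, the highest of any array and channel, so background common to all spots could account for no more than part of it. Cross-hybridisation of Y probes under other wash or labelling conditions stays open, as it was not tested, and no biological explanation besides the sex of the animal was tested.

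Away from called regions the wildtype and flex2/FH-I26A profiles moved together: over 1519 regions of 1 Mb without a call in any tumour their means correlated with r = 0.68 (across regions, which are not independent replicates), and single-probe residuals around the segment means with r = 0.46. Means over 1 Mb also correlated between the wildtype and flex2/flex2 arrays with r = 0.38, so a trend of the probes that every array carries may account for part of the regional pattern, while copy number changes shared by the tumours stay open for it. For single probes such a common trend is argued against by r = 0.00236 between the wildtype and flex2/flex2 arrays. Residuals of each probe and its neighbour on the other array correlated with r = 0.0397. That argues against shared copy number changes over several neighbouring probes as the source of the single-probe correlation. Changes long enough to form segments had been removed from the residuals. Changes confined to a single probe would not raise the value, so it cannot decide on either. What the wildtype and flex2/FH-I26A arrays share by probe, such as labelling or DNA quality acting through probe sequence, stays open because no probe sequence was used. The SD of the 1 Mb means was 0.08 in the wildtype array, where called losses reached -0.21 to -0.38.

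Chromosome 8 of the flex2/flex2 tumour held 39 of 89 breakpoints. Noise cut into segments is argued against by the 29 segments found with a penalty factor of 20, against 40, with 25 of the 39 breakpoints at the same probe, and probes that misreport on every array by the slopes of the other arrays on this tumour's segment means, of which the larger was 0.0802. An even spread of breakpoints over the probes gave at most 18 on any chromosome in 10000 random placements. Clustered rearrangement may be a candidate explanation, as a hypothesis found and tested on the same data, and it need not be limited to this chromosome, since chromosomes 6 and 4 held 15 and 14 breakpoints. Whether it relates to the flex2/flex2 genotype is untested with 1 tumour of it.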

How the results depend on the processing

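Of 264 values, 24 results under 11 alternatives, 224 stayed within 1.5 times the value reported and 40 moved further. None moved with the authors' value table or with segments of at least 3 or at least 10 probes. The value table equalled the scanner's log ratio for at least 99.4% of features of each array, so it was nearly the same input and no independent check. Counts of high-level and deep segments do not use the call threshold, so they could not move with it. The cause was not tested for those that moved, except that a threshold changes calls by construction.

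With a threshold of 0.1 the wildtype tumour had 1730 gained and 40918 lost probes, 25 called segments and 1 whole-chromosome change, against 220, 1916, 9 and 0; the flex2/FH-I26A tumour had 9511 gained and 41198 lost probes and 5 whole-chromosome changes, against 6305, 23544 and 3; and shared losses were 7966 for wildtype and flex2/flex2, 18159 for wildtype and flex2/FH-I26A and 11411 for flex2/flex2 and flex2/FH-I26A, against 328, 0 and 5558 over the common probes of each pair. With a threshold of 0.3 the wildtype tumour had 12 lost probes and 4 called segments, the flex2/flex2 tumour 1 whole-chromosome change against 2, the flex2/FH-I26A tumour 0 gained and 13189 lost probes, 8 called segments against 13 and 0 whole-chromosome changes. Shared losses were then 0 for wildtype and flex2/flex2 and 905 for flex2/flex2 and flex2/FH-I26A, and shared gains of the last pair 0 against 4808.

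With a penalty factor of 5 the wildtype tumour had 5050 lost probes, 17 called segments and 5 lost probes on chromosome 11 against 0, the flex2/FH-I26A tumour had 20 called segments, and shared losses were 647 for wildtype and flex2/flex2 and 1929 for wildtype and flex2/FH-I26A. With a factor of 20 the wildtype tumour had 989 lost probes and 4 called segments, the flex2/FH-I26A tumour had 8 called segments, and shared losses were 0 for wildtype and flex2/flex2 and 2720 for flex2/flex2 and flex2/FH-I26A. With normexp the wildtype tumour had 4145 lost probes, the flex2/flex2 tumour 7 high-level or deep segments against 3, and shared losses were 2065 for wildtype and flex2/flex2 and 11280 for flex2/flex2 and flex2/FH-I26A.

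Centring on the mode gave 1 whole-chromosome change in the flex2/flex2 tumour and 1994 shared gains of flex2/flex2 and flex2/FH-I26A, and keeping spots with outlier marks gave 1 and 2490. With only probes well above background, 88 losses were shared by wildtype and flex2/FH-I26A. The correction for GC content was not run. With 1 array per group, neither a paired analysis between genotypes nor leaving out a replicate was possible. Each ratio already sets a tumour against tail DNA. Signal over background limited few probes, since over 99% were well above background.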

Other observations

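All tests in this part were chosen after the result was seen.

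On chromosome 4 of the flex2/flex2 tumour, gains and losses also lay side by side over short distances. From 73.9 to 92.88 Mb, losses at -0.63, -0.60 and -0.65 were interrupted by the deep losses at -2.15 and -1.91 and by a gain at 0.76 over 1.86 Mb. Chromosome 6 held gains at 0.89 over 2.06 Mb and at 0.85 over 1.4 Mb between losses at -0.59 and -0.58. Chromosomes 4 and 6 held 14 and 15 of the tumour's 89 breakpoints.

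The shallower log2 ratios of the flex2/FH-I26A tumour were set against a model in which a share of the cells of a diploid tumour carries the changes. If the median loss is the loss of a single copy, that share would be 40.9% in the flex2/FH-I26A tumour and 72.2% in the flex2/flex2 tumour. The median gain differed from the gain of a single copy predicted from these shares by -0.0159 and -0.0302 on the log2 scale in the same order, in a comparison that the threshold for calls keeps from failing on the low side in the flex2/FH-I26A tumour. For the flex2/flex2 tumour the predicted loss of both copies was -1.85 relative to its probes without a call. Its 3 deep losses all lay lower, at -2.20 to -1.96 on that scale. They were within 5 SE of the prediction and so were not counted as off level below. Over all segments, called or not, 9.58% of probes in the flex2/FH-I26A tumour and 7.95% in the flex2/flex2 tumour lay in segments more than 0.1 and 5 SE away from no change and from every predicted level. The mean of the wildtype array over each such segment was then subtracted. In the flex2/FH-I26A tumour 1 of 3 segments stayed more than 0.1 away, with 3.11% of probes. In the flex2/flex2 tumour 6 of 9 did, with 4.77%. Segments that the subtraction moved off a level were not counted, so these shares could only fall. Lying under the 5% set for deciding against the model thus decides nothing. In the flex2/flex2 tumour the distance grew on chromosome 9 from 68.82 to 104.23 Mb (0.29 to 0.31) and from 104.24 to 123.96 Mb (0.11 to 0.17). The distance also grew on chromosome 12 from 101.15 to 120.46 Mb (0.13 to 0.22), and it shrank for the other segments off level. Subtracting the wildtype array did not bring these segments on chromosomes 9 and 12 to a level that the model predicts. The first of them was a loss at -0.25, where the wildtype array lay at 0.02. On chromosome 12 the wildtype array lay at -0.09. The array subtracted is the profile of another tumour, so the subtraction cannot tell a trend of the probes from that tumour's own copy number. Compression of ratios was not tested. The model was not set against the wildtype tumour.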
